A study of Mus musculus with 12 samples.

How the data were processed

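Gene expression was measured in splenic germinal centre B cells of mice on 12 Affymetrix 3' expression arrays, 1 array per sample. The samples fell into 5 groups by their labels: control cells sorted from the dark zone (3 arrays) and from the light zone (3 arrays), and total germinal centre cells of the FOXO1, P110* and PTEN mutants (2 arrays each). Per the labels' protocols, cells were sorted by FACS, total RNA was purified with Qiagen RNeasy kits and biotin-labelled with an Affymetrix 3' in vitro transcription kit. The deposited values are log2 expression per probe set, summarised by robust multi-array average (RMA), per the submitters' processing notes, and the version of that software is not given in the sources used here. RMA corrects background, quantile normalises the probes and summarises each probe set. The log2 scale was checked on the values, which ran from 2.00 to 14.8 with 0 missing, and the median of each array lay between 4.83 and 4.93. Raw scanner files were not used here.

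The table held 45101 probe sets, of which 64 were array controls. Gene names came from the platform annotation: 34958 probe sets had 1 gene symbol, 932 had several and 9211 had none. Entrez identifiers of 34754 of the named probe sets were found in a mouse reference gene table (assembly GRCm38.p6), which changed 0 symbols. That table was used only for names and for which genes neighbour each other, since no genome build belongs to the expression values. The named probe sets covered 18194 genes, 9012 of them with more than 1 probe set, and each gene was represented by the probe set with the highest mean over the 12 arrays. Genes were tested when at least 2 arrays exceeded the median of all values in the table (4.89), which kept 11599 genes and left out 6595 as dim. Pten, Aicda and Sell had no probe set under their own name in that annotation and were not analysed here.

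Log2 values were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays, so that all groups shared 1 estimate of the spread (7 residual and 3.72 prior degrees of freedom). Each two-sided moderated test was adjusted by the Benjamini-Hochberg method over the 11599 genes, and a gene is said to differ when its adjusted p was under 0.05. Light zone was compared with dark zone control cells. Since no control array of unsorted zones is among the samples, each mutant was compared with the mean of the dark zone and light zone groups, at a weight of 0.5 each on the log2 scale. A gene lying above, or below, both control zones in separate tests was counted as outside both zones, which no mix of the control zones can give. The mutants were also compared with each other, where the zone sort does not enter the difference, although the shared spread includes the sorted control arrays. The labels do not say whether the arrays of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

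The genes named for each comparison followed a rule fixed before the data were examined. They were the 10 largest and 10 smallest fold changes among genes that differed with non-overlapping arrays, without immunoglobulin segments and placeholder symbols, then 14 fixed genes of germinal centre biology, and up to 4 members of each gene list with the smallest p. For 36 gene lists fixed at the same time, 34 had at least 5 measured members and were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Several lists share members: dark zone markers with G2/M genes, and light zone markers with NF-kB targets and with BCR-induced early response genes. The plasma cell programme shares members with the plasma cell markers and many with the unfolded protein response. BCR-induced early response genes also share members with the heat shock and dissociation stress list. Calls of such lists are not independent. The lists of NK cells (Il2rb, Prf1 and Tbx21 measured) and of neutrophils and monocytes (Mmp9 and S100a9 measured) were too small to test, and the mean of these genes over all arrays was between 4.83 and 7.90 log2 units. Camera asks whether a list shifts more than other genes, and fry whether its members move on balance one way. Where a list is described, the number of members that differed is given over all genes and after adjustment over the list alone.

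Zone position was scored per array as the mean of a set of genes, scaled so that the dark zone control mean was 0 and the light zone control mean was 1. Fold changes of the mutants share the same 6 control arrays, so their correlation and covariance were set beside 100 simulated sets of unchanged mutant arrays and beside 6 splits of the controls with no shared array. The procedure was tested on simulated data in 10 sets with 200 of 11599 genes changed. For light zone against dark zone, 20.2% of genes changed by 1 log2 unit were recovered, 76.8% of those changed by 2 and 89.4% of those changed by 3. The shares at 1, 2 and 3 log2 units were 21.4%, 73.8% and 91.6% for FOXO1, 17.6%, 73.4% and 90.8% for P110*, 22.0%, 70.6% and 93.8% for PTEN, and 8.6%, 58.0% and 82.6% for P110* against FOXO1. False calls made up 4.34% to 4.96% of all calls in these simulations, which gave each gene 1 spread in all groups and independent noise. In the data the median SD over genes was 0.433 in light zone and 0.286 in dark zone controls, against 0.171 to 0.196 in the mutants. The simulated shares therefore do not cover unequal spread. For light zone against dark zone the shared estimate of the spread can be too small, and between mutants it can be too large. The number of arrays limits the precision.

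Alternatives covered the filter, the choice of probe set, scaling, the prior of the test, array weights, the arrays in the fit, a replicate block, the control reference, the list test and the omission of each array. Arrays were also checked for RNA quality, by the difference between 3' and 5' control probe sets of actin, and for the sex of the animals, by Xist and Kdm5d, and alternatives for both were added after seeing the data.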

Results

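Expression arrays were collected from B cells of the mouse spleen germinal centre, the structure in which activated B cells mutate their antibody genes and divide in a dark zone and are selected in a light zone. The series asks how PI3 kinase and the transcription factor FOXO1 act on B cells in these zones. All animals carried the Cγ1-cre driver, a recombinase expressed in B cells that transcribe the IgG1 constant region. Control cells expressed a YFP reporter and were sorted as dark zone (3 arrays) or light zone cells (3 arrays). The mutants were sorted as total germinal centre cells, with 2 arrays each: FOXO1 (floxed Foxo1), PTEN (floxed Pten, the phosphatase that opposes PI3 kinase) and P110*. The p110 protein is the catalytic subunit of PI3 kinase, and the labels do not say what the asterisk stands for. Array medians lay between 4.83 and 4.93 log2 units, and 10233 to 10548 of the 11599 tested genes exceeded the floor on an array. Light zone array 1 had the largest 3' to 5' difference of actin, 2.30 against 1.39 or less elsewhere. The control arrays numbered 2, 1 per zone, carried a male pattern of Xist (3.09 and 2.92 log2 units) and Kdm5d (7.12 and 7.21), and the other 10 arrays a female one.

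The targeted gene was lower in both FOXO1 arrays. Foxo1 stood at 4.90 ± 0.43 log2 units (SD, n = 2) in FOXO1 cells, against 10.77 ± 0.29 (n = 3) in dark zone and 10.58 ± 0.71 (n = 3) in light zone control cells, on the brightest of its 4 probe sets. PTEN cells held 10.74 ± 0.36 (n = 2) and P110* cells 12.40 ± 1.27 (n = 2), from 11.50 on array 1 and 13.29 on array 2. A pair of further Foxo1 probe sets, at 4.84 and 4.49 and at 4.28 and 3.54 in the FOXO1 arrays, were also below all other arrays, which read at least 7.73 and 7.75. The remaining Foxo1 probe set was not lower, at 6.49 and 6.44 in FOXO1 and 6.19 or less elsewhere, and whether it lies in the deleted part is not known here. Pik3ca, which encodes p110α, was 0.36 ± 0.26 log2 units (SE) above the control zones in P110* on its brightest probe set (adjusted p = 0.492). On its other probe sets, untested, the log2 difference ran from -0.175 to 0.754, the highest reading 7.82 and 9.92 on P110* arrays 1 and 2. The labels do not say which p110 gene the P110* allele carries. The PTEN label could not be checked by its gene, since Pten was not analysed here.

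**Figure D1:**
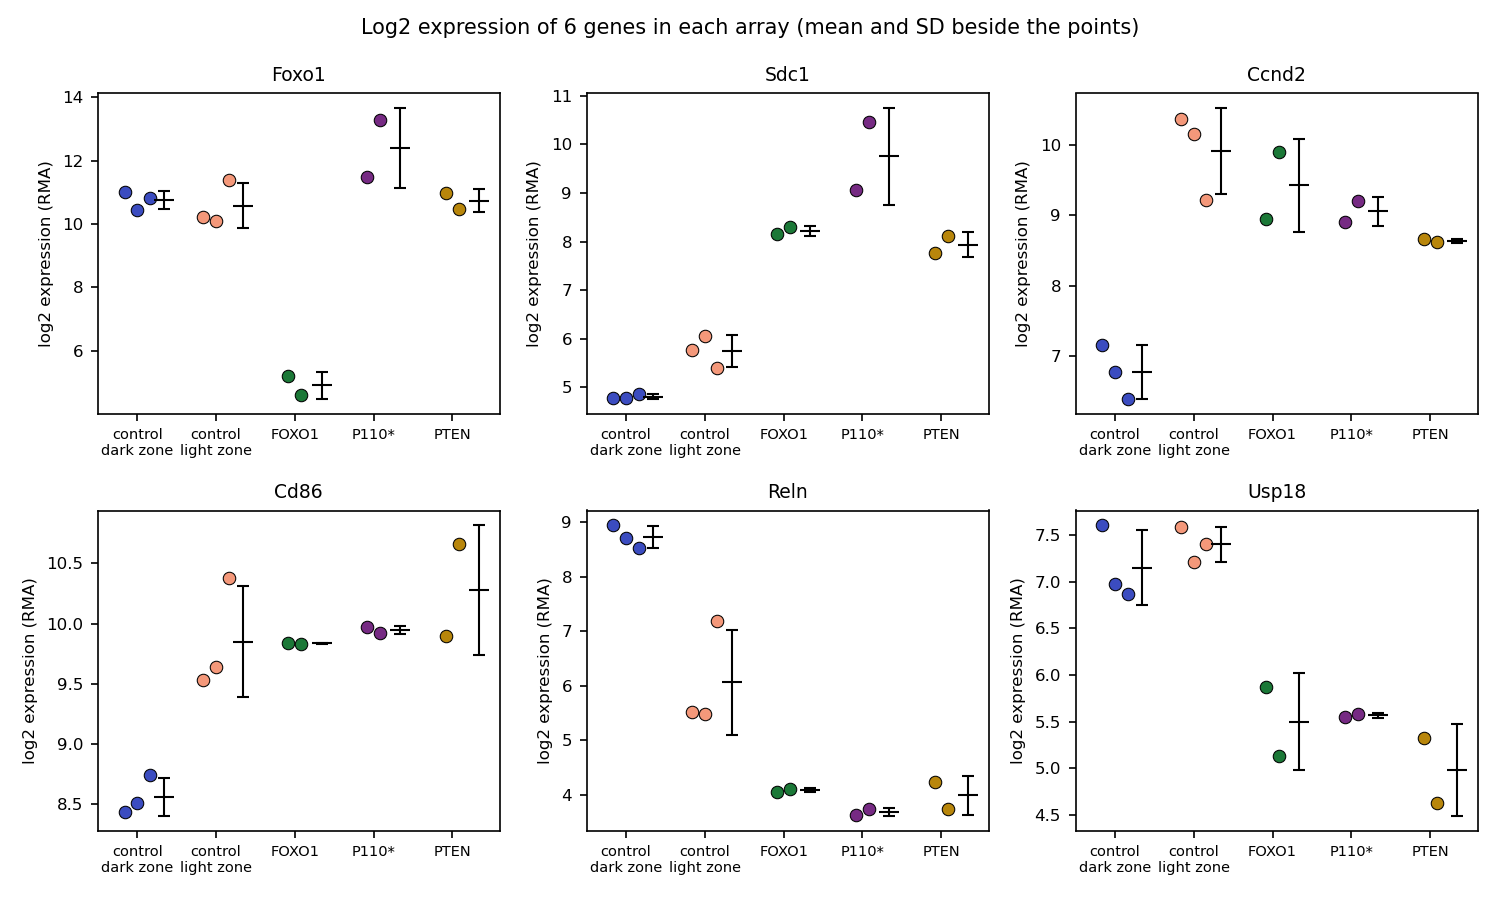
Log2 expression (RMA, vertical axis) of 6 genes on each of the 12 arrays, with the group mean and SD as a bar beside the points of each group on the horizontal axis. The Foxo1 mean is 4.90 in FOXO1 cells, and Sdc1, on its brightest probe set, is at 7.76 or more in all 6 mutant arrays and at 6.06 or less in all 6 control arrays.

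Light zone control cells were compared with dark zone control cells to describe how the zones differ. Light zone cells held 8.85-fold more Ccnd2 mRNA, which encodes the G1 cyclin D2, at 9.92 ± 0.61 log2 units (SD, n = 3) against 6.77 ± 0.38 (n = 3), a log2 difference of 3.15 ± 0.35 (SE, limma adjusted p = 0.0132). Among the other genes higher in the light zone were the transcription factors Egr3 (log2 2.69 ± 0.41), Egr2 (2.25 ± 0.27), Myc (1.88 ± 0.37) and Irf4 (1.64 ± 0.24), the chemokine Ccl22 (2.74 ± 0.39) and the cytokine signalling inhibitor Socs3 (2.58 ± 0.34), with adjusted p from 0.0132 to 0.0491. The list of largest differences also held Rilpl2 (11.8-fold), the fatty acid receptor Ffar2 (8.69-fold), Ephx1, Serpinb1a, the interferon-inducible GTPase Irgm1 and the phosphatase Ptpn22, the last at 5.31-fold. Dark zone cells held more Pdzd3 (27.8-fold), Zkscan16 (log2 -4.04 in the light zone), the glycosyltransferase Gcnt3 (7.72-fold), the secreted glycoprotein Reln (6.34-fold) and Cspp1 (5.59-fold), and between 4.50-fold and 5.41-fold more Trim2, Rhobtb1, Dnase1, Acbd5 and Cdh2. The arrays of the higher group lay far apart for Pdzd3 (SD 2.04 log2 units), Rilpl2 (1.76), Ffar2 (1.11), Zkscan16 (1.10) and Ptpn22 (1.01). The lower of the compared means was under the floor of 4.89 for Ccl22, Serpinb1a, Irgm1, Ptpn22, Zkscan16, Trim2, Rhobtb1 and Cdh2, so the size of these differences is uncertain. In all, 95 of 11599 genes differed, 65 higher in the light zone and 30 higher in the dark zone. The arrays of both groups did not overlap for any of the 95. Chance gives this separation for 10% of unselected genes, but these were selected on the same arrays, so it adds no support.

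Light zone markers were higher as a list, with 7 of 34 measured members higher and 0 lower over all genes, and 18 higher adjusted over the list alone (camera adjusted p = 1.41e-14; adjusted p = 0.0479 with an estimated correlation). MYC targets and ribosome biogenesis genes were higher too, 3 of 34 and 10 of them adjusted over the list alone, among them the spermidine synthase Srm (log2 1.78), the helicase Ddx21 (1.29) and the chaperone Hspd1 (1.35). Camera gave adjusted p = 1.9e-09 for that list, and adjusted p = 0.15 with an estimated correlation. NF-kB targets were higher in 3 of 28 members, Ccl22, Irf4 and Tnfaip3 (1.25), and in 11 adjusted over the list alone (adjusted p = 1.01e-07; 0.0825 with an estimated correlation). Of the BCR-induced early response genes, Egr2, Egr3 and Myc were higher and 3 of 22 differed, or 6 higher and 1 lower adjusted over the list alone, the lower one being the phosphatase Dusp5 at log2 -1.86 (camera adjusted p = 0.0238; adjusted p = 0.337 with an estimated correlation). Dark zone markers were lower in the light zone, with Gcsam at log2 -1.73 ± 0.23 the 1 of 33 members that differed and 2 adjusted over the list alone (adjusted p = 3.19e-06; 0.15 with an estimated correlation). Genes of G2/M and mitosis, many of them also dark zone markers, were lower as well, Ttk (log2 -1.30) being the 1 of 37 members that differed and 2 adjusted over the list alone (adjusted p = 1.4e-05; 0.234 with an estimated correlation).

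Further lists were called higher in the light zone with at most 1 member past the threshold each. Antigen presentation genes of MHC class II had 0 of 20 members past the threshold and 4 adjusted over the list alone, with Cd86 at log2 1.29 (adjusted p = 0.0682) and Ifi30 at 1.28 (0.109). The list gave camera adjusted p = 0.00831, and adjusted p = 0.15 with an estimated correlation. The unfolded protein response had 0 of 27 past the threshold and 5 adjusted over the list alone (adjusted p = 0.00831; 0.288 with an estimated correlation). Markers of naive, follicular and marginal zone B cells had 0 of 13 and 4 adjusted over the list alone (0.00932; 0.288 with an estimated correlation). The plasma cell programme had 1 of 28, Irf4, and 5 adjusted over the list alone (0.0133; 0.288 with an estimated correlation). Glycolysis had 1 of 19, the aldolase Aldoc at log2 1.20, and 3 adjusted over the list alone, ATF4 targets 0 of 28 and 2, and apoptosis regulators 0 of 22 and 0, each with camera adjusted p = 0.0238. With an estimated correlation these 3 lists gave adjusted p = 0.288, 0.288 and 0.15. Dendritic cell markers were not called (0.0643), although Ccl22, Ffar2 and Bst2 (log2 1.10) were higher among their 11 measured members. Of the fixed genes that separate the zones at the surface, Cxcr4 was log2 -0.77 ± 0.48 (SE, adjusted p = 0.496) and Cd83 0.87 ± 0.22 (0.107) in the light zone relative to the dark zone. Foxo1, Bcl6, Bach2, Klf2, Prdm1 and Pik3ca did not differ, with adjusted p from 0.168 to 0.902.

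The number of zone genes depended on single arrays. It was 195 without light zone array 2, 58 without either FOXO1 array, 44 without either PTEN array and 41 without either P110* array. It was 32 without dark zone array 1, 25 without dark zone array 2 and 23 without dark zone array 3. It was 15 with array weights, 61 with the most variable probe set per gene, 54 without both male arrays and 174 with the male pattern as a covariate (the last 2 chosen after seeing the data). It was 0 in limma fitted to the 6 control arrays alone, where 1200 genes had an unadjusted p under 0.05 against 1725 in the fit of all arrays. The share of zone genes higher in the light zone was 68.4% as deposited, 56.0% after a further quantile normalisation and 48.4% after centring each array on its median, which moved the median difference of all genes from 0.0549 to -0.0968. The 13 called lists kept their direction under both scalings, and 8 were called without light zone array 3.

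FOXO1 cells were compared with the mean of the control zones to ask what changes when Foxo1 is deleted. Next to Foxo1 itself (log2 -5.77 ± 0.47 SE, adjusted p = 0.000712), the plasma cell surface proteoglycan Sdc1 (syndecan-1) was 7.69-fold higher, at 8.22 ± 0.10 log2 units (SD, n = 2) against 4.81 ± 0.05 (n = 3) in dark zone and 5.75 ± 0.33 (n = 3) in light zone cells (adjusted p = 0.00237). On another of the 4 Sdc1 probe sets the log2 difference from the control zones was 2.54 in FOXO1, 4.29 in P110* and 2.08 in PTEN, with light zone array 1 at 7.27 and PTEN array 1 at 6.03. It was 0.58, 1.47 and 0.59 on the next and -0.18, 0.18 and 0.10 on the last, and these probe sets were not tested. Pik3ap1, the adaptor that links the B cell receptor to PI3 kinase, rose 7.65-fold (adjusted p = 0.000712). The lipase Mgll (22.3-fold), Gdpd3 (8.92-fold), the endoplasmic reticulum protein Ckap4 (7.28-fold), the secreted protease inhibitor Slpi (6.70-fold), the matrix protein Emilin2 (6.47-fold) and the secretory cell transcription factor Bhlha15 (6.19-fold) also rose, as did Tmem219 and Lrba. The FOXO1 arrays lay far apart for Mgll (SD 2.10 log2 units), Tmem219 (2.10), Lrba (1.72) and Bhlha15 (1.19). Genes that fell included Mndal (log2 -3.86), Mup10 (-3.53), Ankrd16 (-3.40) and Reln (-3.31). They also included the peptide transporter Slc15a2 (-3.17), the GABA receptor subunit Gabbr1 (-3.09), Pdzd2 (-2.97), the ecto-nucleotidase Nt5e (-2.92) and Slc9a5 (-2.90), of which Mndal, Pdzd2 and Nt5e had an SD of 3.16, 2.08 and 1.29 in FOXO1. The lower of the compared means was under the floor for Emilin2, Mup10, Reln, Nt5e and Slc9a5 and beside it for Foxo1, so the size of these differences is uncertain. In all, 423 genes differed, 120 higher and 303 lower, and for 413 of them both FOXO1 arrays lay on 1 side of all 6 control arrays. Chance gives this for 7.14% of unselected genes, but these were selected on the same arrays, so it adds no support. Against each zone separately, 135 genes lay outside both control zones, 41 above and 94 below.

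Interferon response genes fell as a list in FOXO1 cells. Of 22 measured members 6 fell and 0 rose, and 9 fell adjusted over the list alone, among them the interferon-induced genes Usp18 (log2 -1.78 ± 0.30 SE), Stat2 (-1.41 ± 0.23), Trim30a (-1.35 ± 0.20) and Mx1 (-1.25 ± 0.23). Camera gave adjusted p = 4.31e-07, and adjusted p = 0.533 with an estimated correlation. BCR-induced early response genes fell in 4 of 22 members, or 7 adjusted over the list alone: the phosphatases Dusp4 (-1.37) and Dusp6 (-1.85), the RNA-binding protein Zfp36 (-1.54) and the nuclear receptor Nr4a3 (-1.71). That list had camera adjusted p = 0.00197, and adjusted p = 0.533 with an estimated correlation. Dark zone markers were lower (adjusted p = 0.0189; 0.533 with an estimated correlation), with Gcsam (-1.17) and Foxp1 (-0.94) lower and the mitotic gene Hmmr (1.57) higher among 33, or 5 lower and 1 higher adjusted over the list alone. On its most variable probe set Hmmr was instead at log2 -0.1646. The plasma cell programme rose (adjusted p = 0.00135; 0.533 with an estimated correlation), with 2 of 28 members higher, Sdc1 and the folding enzyme Fkbp11 (1.96), and 6 higher and 1 lower adjusted over the list alone. In the shorter list of plasma cell markers Sdc1 was the 1 of 10 that rose, with 3 adjusted over the list alone (adjusted p = 0.0189; 0.533 with an estimated correlation). Tnfrsf17 was 9.18 log2 units on FOXO1 array 1 and 5.02 on array 2. For Mx1, Dusp4, Nr4a3 and Fkbp11 the lower mean was under the floor. Oxidative phosphorylation genes were shifted up with 0 of 34 past the threshold and 0 adjusted over the list alone (adjusted p = 0.0189; 0.535 with an estimated correlation). The fixed FOXO target list was not called (adjusted p = 0.321), with the insulin receptor Insr (-1.40) and Trib2 (-1.03) lower and Gabarapl1 (0.90) higher among 29. Of the fixed single genes, Cxcr4 was log2 -1.07 ± 0.48 (adjusted p = 0.271), Cd86 0.63 ± 0.28 (0.261), Pik3ca 0.96 ± 0.26 (0.0697), and Cd83, Bcl6, Myc, Bach2, Klf2, Irf4 and Prdm1 had adjusted p from 0.188 to 0.988. Other Pik3ca probe sets, untested, went both ways in FOXO1, at log2 0.62, 0.53, -0.45, -0.49 and -0.55. The number of genes that differed in FOXO1 was 108 without FOXO1 array 2, 170 without FOXO1 array 1, 261 without dark zone array 3 and 273 without either P110* array. It was 168 with the FOXO1 and control arrays alone and 650 with array weights. The 135 genes outside both zones became 37, 78 and 67 without FOXO1 array 2, FOXO1 array 1 and dark zone array 3, 78 without either P110* array, 88 without either PTEN array, 74 with array weights and 20 with the FOXO1 and control arrays alone.

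P110* cells were compared with the control zones in the same way, to ask what follows a change in PI3 kinase itself. Sdc1 rose 22.3-fold, to 9.76 ± 0.99 log2 units (SD, n = 2; adjusted p = 0.000262), and Cln8, a membrane protein of the endoplasmic reticulum, rose 21.1-fold (adjusted p = 0.000823). Ankrd52 (11.6-fold), Mgll (11.4-fold), Ppfia4 (9.29-fold), the folliculin partner Fnip2 (8.73-fold), the sialyltransferase St3gal1 (8.67-fold), the growth factor Bmp8a (8.40-fold), the acyltransferase Agpat4 (8.23-fold) and Slpi (8.15-fold) rose as well. The P110* arrays lay far apart for Ankrd52 (SD 1.37 log2 units) and Cln8 (1.06). On its other probe sets the log2 difference of Sdc1 was 4.29, 1.47 and 0.18, untested. The G protein subunit Gnaz fell by 4.73 log2 units (± 0.76 SE, adjusted p = 0.00567). Lmo7 (-4.24), Slc15a2 (-3.96), the receptor kinase Ltk (-3.78), Reln (-3.71) and the B cell co-receptor Cd72 (10.9-fold) fell as well. Mup10, Dtx3, Trpm5 and Lmo4 fell too, between 9.73-fold and 10.8-fold. The lower of the compared means was under the floor for Fnip2, Reln, Mup10, Trpm5 and Lmo4, so the size of these differences is uncertain. The transcription factor Prdm1, which drives plasma cell differentiation, rose 2.83-fold (adjusted p = 0.00844), to 8.11 ± 0.35 (SD, n = 2) from 6.18 ± 0.32 in dark zone and 7.03 ± 0.17 in light zone cells. In all, 735 genes differed, 229 higher and 506 lower, and 711 of them had both P110* arrays on 1 side of all control arrays. The 7.14% that chance gives holds for unselected genes, so this separation adds no support. Outside both control zones lay 301 genes, 91 above and 210 below.

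In P110* the plasma cell programme rose, with 5 of 28 members higher and 2 lower, and 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000164; adjusted p = 0.376 with an estimated correlation). Its members included Fkbp11 (log2 2.65), the chaperone Hsp90b1 (1.70) and Prdm1, while the plasma cell surface receptor Slamf7 fell by 1.47. The plasma cell marker list gave 2 of 10 higher and 1 lower, or 4 and 1 adjusted over the list alone (0.0188; 0.376 with an estimated correlation). The unfolded protein response had 2 of 27 higher, Hsp90b1 and Dnajc3 (0.99), with 2 adjusted over the list alone (0.0246; 0.496 with an estimated correlation). Interferon response genes fell in 5 of 22 members, including Mx1 (-2.09), Xaf1 (-1.86) and Usp18 (-1.71), and in 10, with 1 higher, adjusted over the list alone (adjusted p = 0.000344; 0.376 with an estimated correlation). Both zone marker lists were lower. Dark zone markers fell in 4 of 33, Gcsam (-2.61), Foxp1 (-2.25), Mybl1 (-1.31) and Foxm1 (-0.92), and 7 adjusted over the list alone (0.00159; 0.376 with an estimated correlation). Light zone markers fell in 5 of 34, among them Egr2 (-1.64), Tnfaip3 (-1.47) and the IgE receptor Fcer2a (-2.19), with 6 lower and 1 higher adjusted over the list alone (0.0226; 0.407 with an estimated correlation). NF-kB targets fell in 6 of 28, including Bcl3 (-2.03), Birc2 (-2.03) and Irf1 (-1.30), with 6 lower and 2 higher adjusted over the list alone (0.0226; 0.376 with an estimated correlation). Genes of somatic hypermutation and class switching fell in 3 of 27, the polymerase Poli (-1.59), Rnf8 (-0.99) and Paxip1 (-1.03), and 4 adjusted over the list alone (0.0226; 0.376 with an estimated correlation). BCR-induced early response genes fell in 2 of 22, Dusp4 (-1.43) and Egr2, and 3 adjusted over the list alone (0.0421; 0.496 with an estimated correlation). Oxidative phosphorylation was shifted up with 0 of 34 past the threshold and 0 adjusted over the list alone (0.0226; 0.554 with an estimated correlation). Macrophage markers moved in the same arrays: the growth factor receptor Csf1r rose by log2 2.79 ± 0.48, the 1 of 8 that differed, with 3 adjusted over the list alone (0.0226; 0.376 with an estimated correlation). For Fkbp11, Mx1, Dusp4 and Csf1r the lower mean was under the floor. The macrophage list mean was 6.07 and 6.23 in P110* and 5.10 to 5.87 in control arrays. With the most variable probe set per gene, 6 lists were called in P110* in place of 11.

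Among the fixed genes in P110*, Foxo1 (log2 1.73 ± 0.47, adjusted p = 0.0575), Cxcr4 (-1.72 ± 0.48, 0.0623) and Irf4 (0.89 ± 0.24, 0.0529) lay just outside the threshold, and Cxcr4 was 9.61 log2 units on P110* array 1 and 12.01 on array 2. On the other Foxo1 probe sets the log2 difference in P110* was 0.453, -0.129 and 0.434, untested, so most of its probe sets did not show that rise. Cd83, Cd86, Bcl6, Myc, Bach2 and Klf2 did not differ (adjusted p 0.164 to 0.971). The number of genes that differed in P110* was 110 without P110* array 2, 213 without P110* array 1, 470 with the P110* and control arrays alone and 1491 with array weights. The 301 genes outside both zones became 48 and 92 without those P110* arrays, 195 without dark zone array 3, 466 with array weights and 185 with the P110* and control arrays alone. The share of genes higher in P110* was 31.2% as deposited, 44.3% after a further quantile normalisation and 50.9% after median centring, which moved the median of all genes from -0.025 to 0.139, and all 11 called lists kept their direction.

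PTEN cells were compared with the same control zones. Sdc1 rose 6.33-fold (adjusted p = 0.00891), to 7.94 ± 0.26 log2 units (SD, n = 2), and Slpi 6.35-fold (adjusted p = 0.0231). Further genes that rose were Pdss2, an enzyme of coenzyme Q synthesis (7.89-fold), Trim68 (6.57-fold), Cfap298 (5.73-fold), the sulfotransferase Chst15 (5.43-fold), the sphingosine phosphate receptor S1pr3 (4.87-fold), Ckap4 (4.86-fold), Dennd11 (4.79-fold) and Zfp827 (4.69-fold). The PTEN arrays lay far apart for Cfap298 (SD 1.57 log2 units) and Zfp827 (1.12). Gnaz fell by 3.89 log2 units (± 0.76 SE, adjusted p = 0.0491). Lmo7 (11.1-fold), Reln (-3.41), the tryptophan-degrading enzyme Ido1 (-3.12), Ankrd33b (-3.10) and the interferon-inducible GTPase Gbp3 (-2.92) fell. So did Lmo4 (-2.88), Nt5e (-2.77), Evc (-2.40) and Gimap7 (-2.35). The lower of the compared means was under the floor for Zfp827, Reln, Ido1, Lmo4, Nt5e and Evc, so the size of these differences is uncertain. In all, 87 genes differed, 42 higher and 45 lower, and 25 lay outside both zones, 15 above and 10 below. All 87 had both PTEN arrays on 1 side of the control arrays, which adds no support, since chance gives 7.14% only for unselected genes.

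Interferon response genes fell as a list in PTEN cells (camera adjusted p = 9.51e-08; adjusted p = 0.388 with an estimated correlation), Usp18 at log2 -2.30 ± 0.30 being the 1 of 22 that passed over all genes, with 9 lower and 1 higher adjusted over the list alone. Dark zone markers fell (0.000373; 0.421 with an estimated correlation), with Gcsam (-1.39) the 1 of 33 and 4 adjusted over the list alone. Genes of G2/M and mitosis were shifted down with 0 of 37 past the threshold and 0 adjusted over the list alone (0.00418; 0.591 with an estimated correlation). Oxidative phosphorylation was shifted down, with 0 of 34 and 0 adjusted over the list alone (0.00411; 0.666 with an estimated correlation). ATF4 targets fell, with the asparagine synthetase Asns (-1.28) the 1 of 28 in both counts, the latter adjusted over the list alone (0.00494; 0.436 with an estimated correlation). The plasma cell programme rose in 2 of 28, Sdc1 and Fkbp11 (1.82), with 5 higher and 1 lower adjusted over the list alone (0.00211; 0.436 with an estimated correlation). The shorter list of plasma cell markers was not called (camera adjusted p = 0.249), with Sdc1 the 1 of 10 that rose, and 2 higher and 1 lower adjusted over the list alone. Macrophage markers were higher, with 0 of 8 past the threshold, Csf1r (2.28, adjusted p = 0.0677) the 1 adjusted over the list alone (0.0112; 0.388 with an estimated correlation), and a list mean of 6.164 and 6.002 in PTEN. For Fkbp11 and Csf1r the control mean was under the floor. Of the fixed genes, Irf4 was log2 1.03 ± 0.24 (adjusted p = 0.0943) and Cd86 1.08 ± 0.28 (0.127), and Foxo1, Pik3ca, Cxcr4, Cd83, Bcl6, Myc, Bach2, Klf2 and Prdm1 had adjusted p from 0.167 to 0.998. The 87 genes became 37 without dark zone array 1, 40 without dark zone array 3, 48 without either P110* array, 50 without either FOXO1 array and 132 without light zone array 2. They became 141 without both male arrays and 132 with the male pattern as a covariate (both chosen after seeing the data), and 55 with the most variable probe sets, 19 with the PTEN and control arrays alone and 178 with array weights. The 25 outside both zones became 6, 16 and 12 without dark zone arrays 1, 2 and 3 and 11 without either FOXO1 or either P110* array, and were 6 with the PTEN and control arrays alone and 15 with the most variable probe sets.

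The mutants were placed on the axis from dark zone (0) to light zone (1) with the fixed marker lists, which were not chosen on these arrays. On the light zone markers, P110* cells stood at 0.088 ± 0.0213 (SD, n = 2), FOXO1 cells at 0.262 ± 0.0205 and PTEN cells at 0.469 ± 0.116. On the dark zone markers, where 1 again stands for the light zone level, they stood at 1.68 ± 0.134, 1.17 ± 0.293 and 1.38 ± 0.00707 in the same order. The light zone control arrays themselves lay at 0.735, 0.926 and 1.34 on these markers. FOXO1 arrays, at 0.966 and 1.38, were thus within or just past that range, and PTEN arrays, at 1.38 and 1.39, just past it. The P110* arrays lay further out, at 1.59 and 1.78. With the 65 light zone and 30 dark zone genes found above, the positions were 0.736 ± 0.0318 in FOXO1, 0.795 ± 0.0127 in P110* and 0.584 ± 0.0382 in PTEN, a set chosen on these control arrays. Its light zone genes alone gave 0.48, 0.382 and 0.315 in that order, and its dark zone genes alone 0.957, 1.15 and 0.816. Both fixed lists together gave 0.521, 0.543 and 0.73, so the order of the mutants depended on the genes used. Control arrays scored with genes chosen without their own number lay at 0.25 to 0.344 (dark zone) and 0.726 to 0.812 (light zone), from as few as 3 light zone and 4 dark zone genes. Of the 30 dark zone genes, 12 were lower than the control zones in FOXO1, 16 in P110* and 6 in PTEN, and 0, 1 and 0 were higher. Of the 65 light zone genes, 3, 11 and 4 were lower and 0, 2 and 1 higher.

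**Figure D2:**
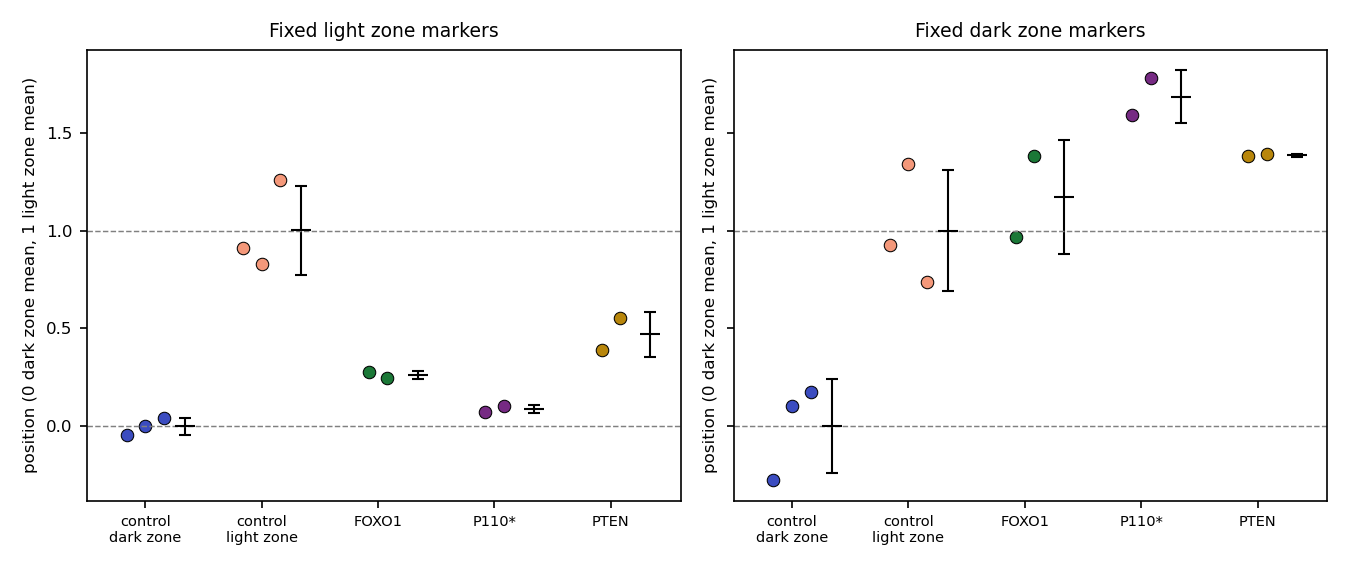
Position of each array on the fixed light zone markers (left) and fixed dark zone markers (right), on a scale where the dark zone control mean is 0 and the light zone control mean is 1, with the group mean and SD beside the points. The P110* arrays are near 0.088 on light zone markers and near 1.68 on dark zone markers.

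**Figure D3:**
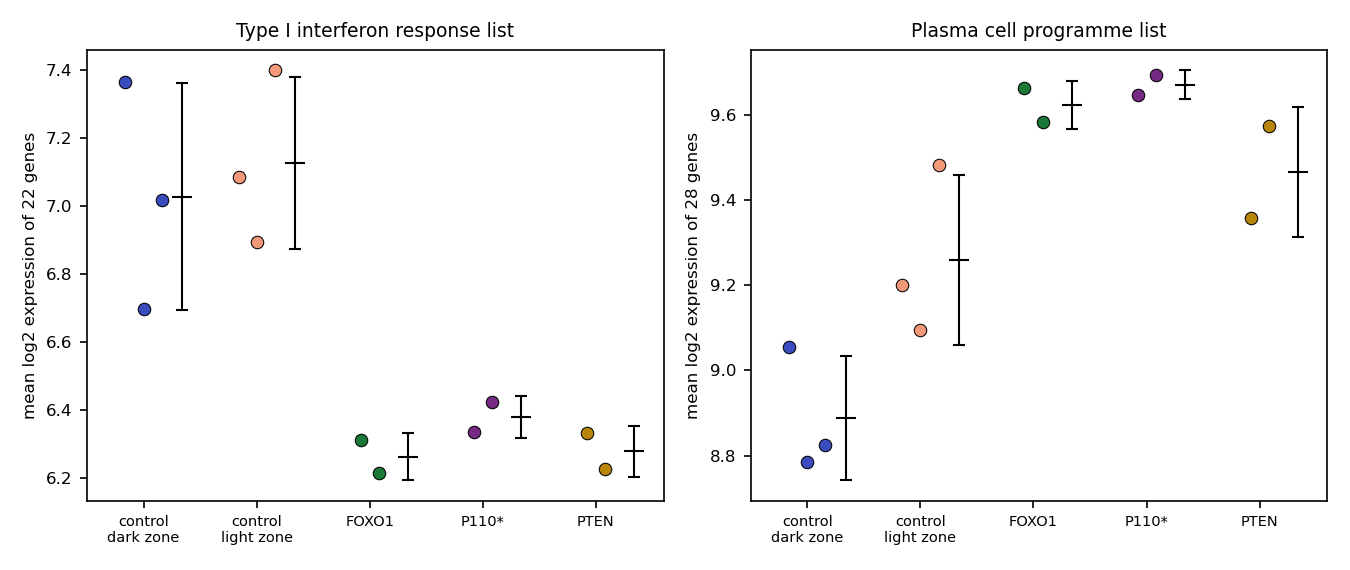
Mean log2 expression per array (vertical axis) of the 22 measured interferon response genes (left) and the 28 measured plasma cell programme genes (right) by group, with the group mean and SD beside the points. All 6 mutant arrays lie at or below 6.42 and all 6 control arrays at or above 6.70 on the interferon list.

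FOXO1 and P110* cells shared 281 of their 423 and 735 genes in the same direction, 49 higher and 232 lower with 1 opposite. The opposite one was the phosphatase Ctdsp2, at log2 1.02 in FOXO1 and -0.96 in P110*, named after its values were seen. Independent lists of that size would share 2.37 and 13.2 genes. The excess of lower genes in each mutant shrank under other scalings. The share of called genes that were higher in FOXO1 was 28.4% as deposited, 34.5% after a further quantile normalisation and 37.9% after median centring. In P110* these shares were 31.2%, 44.3% and 50.9%. Fold changes across the 11599 genes correlated at r = 0.722, against 0.25 on average in simulated unchanged mutants that share the 6 control arrays. The covariance was 0.314 against 0.0357, a difference of 0.278. Those simulations gave each gene 1 spread in all groups, while control arrays spread more than mutant arrays. The simulated r and covariance can therefore be too low for every pair of mutants, and that difference too large. With the controls split so that no array was shared, 152 genes on average (82 to 195) were shared, the mean r was 0.507 and the covariance was 0.256. FOXO1 and PTEN shared 35 genes, 14 higher and 21 lower (0.435 and 1.18 by independence) with 2 opposite, Csf2ra (-0.88 and 1.06) and Trim68 (-1.86 and 2.72), named after their values were seen, at r = 0.263 against 0.247 simulated and a covariance of 0.0907 against 0.0354. P110* and PTEN shared 59, 22 higher and 37 lower with 0 opposite (0.829 and 1.96 by independence), at r = 0.402 against 0.25 and a covariance of 0.148 against 0.0356. With split controls the last 2 pairs shared 20.7 and 35.7 genes on average, with a mean r of 0.0813 and 0.206 and a covariance of 0.0325 and 0.0894. Genes are not independent replicates, so no p is given for these values. The 281 shared genes became 44 without FOXO1 array 2, 81 without FOXO1 array 1, 66 without P110* array 2, 88 without P110* array 1, 184 without dark zone array 3 and 480 with array weights. The 35 of FOXO1 and PTEN became 4 without PTEN array 2 or FOXO1 array 2, 9 without PTEN array 1, 15 without FOXO1 array 1, 18 and 20 without dark zone arrays 1 and 3. The 59 of P110* and PTEN became 12 and 18 without PTEN arrays 2 and 1, 24 and 27 without P110* arrays 2 and 1, 29 without dark zone array 1 or 3 and 38 without either FOXO1 array.

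**Figure D4:**
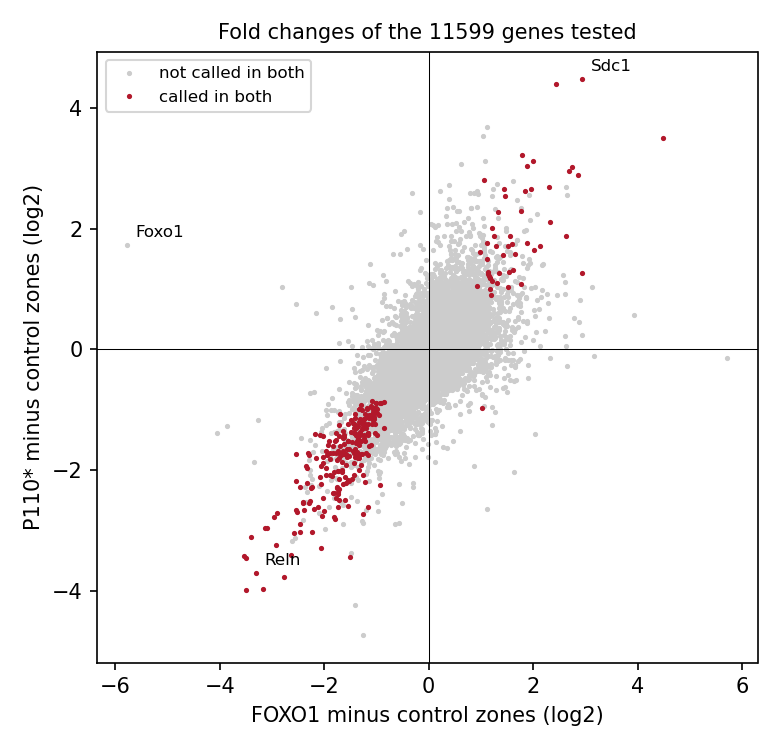
Log2 fold change of each of the 11599 genes in P110* (vertical axis) against FOXO1 (horizontal axis), both minus the mean of the control zones, with genes that differed in both comparisons in red. Fold changes correlate at r = 0.722, part of which comes from the shared control arrays, and Foxo1 lies apart at -5.77 in FOXO1.

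P110* cells were compared directly with FOXO1 cells, both sorted as total germinal centre cells. Foxo1 was higher in P110* (log2 7.50 ± 0.58 SE, adjusted p = 0.000394), by an uncertain amount, since its mean in FOXO1 (4.90) lay beside the floor of 4.89. The gap was smaller on other Foxo1 probe sets. They read 8.81 and 8.31 in P110* against 4.84 and 4.49 in FOXO1, and 8.58 and 8.35 against 4.28 and 3.54. The last probe set read 5.71 and 6.19 in P110* against 6.49 and 6.44. The complement inhibitor Cd59a was 4.81-fold higher in P110*, at 9.005 ± 0.23 log2 units (SD, n = 2) against 6.74 ± 0.09 (n = 2) in FOXO1 (adjusted p = 0.00905), and Osgin1 was 5.32-fold higher (adjusted p = 0.00946). Rgcc, a regulator of the cell cycle, was 13.5-fold higher in FOXO1 at 10.20 ± 0.65 against 6.44 ± 0.49 (adjusted p = 0.00252), the recombination gene Mnd1 4.96-fold higher (adjusted p = 0.0141) and the phosphatase Ctdsp2 3.95-fold higher (adjusted p = 0.0333). The shared spread, which includes the control arrays, can be too large here, so the number of genes called does not measure how alike these mutants are. Altogether 8 genes differed, 4 higher and 4 lower, all with arrays that did not overlap. Chance gives this for 33.3% of unselected genes at n = 2 against 2, so it adds no support for these selected ones. The plasma cell gene Prdm1 was log2 1.06 ± 0.32 higher in P110* without passing (adjusted p = 0.614), and Pik3ca, Cxcr4, Cd83, Cd86, Bcl6, Myc, Bach2, Klf2 and Irf4 each had adjusted p = 0.999. None of the 34 lists was called by camera, with an estimated correlation or by fry, and the lowest adjusted p with an estimated correlation was 0.673. In limma 559 genes had an unadjusted p under 0.05. The number that differed was 43 without FOXO1 array 1, 39 without FOXO1 array 2, 16 without P110* array 1, 59 with array weights and 0 with the 4 mutant arrays alone, where 1060 genes had an unadjusted p under 0.05. Median centring moved the median difference of all genes from -0.0536 to 0.0727.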

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

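The tests of plasma cell genes against both zones and of the dim plasma cell markers with Jchain, the gene lists in PTEN against FOXO1 and in P110* against PTEN, the probe sets without a single gene name and the gene counts with the actin covariate came from tests chosen only after the result was seen.

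In direct tests between the mutants, limma called 8 genes in P110* against FOXO1, 168 in PTEN against FOXO1 (143 higher, 25 lower in PTEN) and 192 in P110* against PTEN (10 higher, 182 lower in P110*). The last contrast had 28 higher and 190 lower after a further quantile normalisation and 22 and 149 after median centring, or 12.8% and 12.9% higher against 5.21% as deposited. Fits of only the 4 arrays compared called 0, 0 and 108, with 1060 and 2646 genes at an unadjusted p under 0.05 in the contrasts with 0, and array weights gave 59, 757 and 992. The 168 became 270 after a further quantile normalisation, 297 after median centring and 264 with the actin difference as a covariate. The 192 became 126 with the most variable probe set per gene and 308 with that covariate. The 168 became 75 and 85 without FOXO1 arrays 1 and 2, 76 and 99 without PTEN arrays 2 and 1, 83 without either P110* array, 104 without dark zone array 1, 258 without light zone array 1 and 316 without light zone array 3. The 192 became 1 and 28 without P110* arrays 2 and 1, 50 and 122 without PTEN arrays 2 and 1, 127 without dark zone array 1, 298 without light zone array 1 and 290 without light zone array 3. The 8 became 43 and 39 without FOXO1 arrays 1 and 2 and 16 without P110* array 1. Oxidative phosphorylation genes, shifted up in FOXO1 and P110* and down in PTEN, differed between PTEN and FOXO1 (median log2 -0.612, camera adjusted p = 2.79e-05; adjusted p = 0.879 with an estimated correlation) and between P110* and PTEN (median 0.559, adjusted p = 7.39e-06; adjusted p = 0.594 with an estimated correlation), with 0 members past the threshold in limma. BCR-induced early response genes were shifted up in PTEN against FOXO1 (median 0.796, camera adjusted p = 3.8e-05; adjusted p = 0.803 with an estimated correlation) and down in P110* against PTEN (median -0.632, adjusted p = 0.00165; adjusted p = 0.594 with an estimated correlation), with 0 of 22 members past the threshold in both. Light zone markers were shifted down in P110* against PTEN (median -0.391, adjusted p = 0.0447; adjusted p = 0.594 with an estimated correlation), with 0 of 34 past the threshold.

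Probe sets without a single gene name, outside the gene comparisons, also differed from the control zones. Of 4609 tested, 152 differed in FOXO1 (64 higher, 88 lower), 479 in P110* (349 higher, 130 lower) and 23 in PTEN (15 higher, 8 lower), against 1 between the control zones.

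The 95 genes of light zone against dark zone came from 1 of the 10 splits of the 6 control arrays, and the highest of the other splits called 0. With 10 splits no share under 0.05 can be reached.

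FOXO1 and P110* shared much of their fold changes, with a covariance of 0.314. Shared control arrays as the whole source were argued against by the splits with no shared array, where the mean covariance was 0.256 and the highest simulated one with no effect was 0.04. Without both male control arrays the covariance was 101% of that value, and with the actin difference as a covariate 106%, against the sex of the control animals or RNA quality as its source. Differences of strain background, housing or batch, which the labels do not give, and the zone sort that only the controls went through, stay open. That both mutants act on the same genes is therefore a hypothesis.

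Interferon response genes were lower in all 3 mutants, with the list mean at 6.213 to 6.423 in the 6 mutant arrays and 6.698 to 7.399 in the 6 control arrays. A few deviating control arrays were argued against, since 0 of the 6 lay at or under the highest mutant array. The list median without both male control arrays was at least 102% of its value in each mutant, and with the actin difference as a covariate at least 101%. The list's call was lost with an estimated correlation in all 3 mutants, and kept by fry (adjusted p = 0.037, 0.0124 and 0.0453 in FOXO1, P110* and PTEN). A difference in housing, batch or strain between control and mutant animals stays open, as does the zone sort that only the controls went through. The calls in the 3 mutants rest on the same 6 control arrays, so they are not independent.

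The plasma cell programme was called higher in all 3 mutants, led by Sdc1, and each call was lost with an estimated correlation (adjusted p = 0.533, 0.376 and 0.436 in FOXO1, P110* and PTEN). By fry the adjusted p was 0.0479, 0.0124 and 0.0956 in that order, so the call was kept in FOXO1 and P110* and lost in PTEN. A shifted mix of the control zones could give members that lie between the zones. Of the 5 programme members higher in P110*, 60% (Sdc1, Fkbp11 and Hsp90b1) passed the threshold above both zones, and Prdm1 and Tnfrsf13b did not pass against both. The P110* mean of Prdm1 still lay above its highest control array (7.15), so missing the threshold does not place it between the zones. The mix stays open for part of the list. Admixed plasma cells may bring their markers together: of the 3 markers dim in the controls (Prdm1, Sdc1 and Tnfrsf17), 1 was higher in all 6 mutant than in all 6 control arrays on its brightest probe set, which is too few markers to decide. Outside that list, single probe sets separated likewise for Bhlha15 (5.70 or more against 5.41 or less), Ighm (6.935 against 6.149) and Ighg3 (10.51 against 10.41). The other probe sets of these genes and those of Igha did not. These genes were named after their values were seen, and the separation was not tested. The FACS sort of germinal centre B cells would be expected to remove plasma cells, but the labels do not give its markers. The abundant plasma cell transcript Jchain had a lowest mutant array of 12.5 and a highest control array of 12.6, and differentiation of the mutant cells and admixture cannot be told apart here.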

How the results depend on the processing

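The settings without both male control arrays and with the male pattern or the actin difference as a covariate were tests chosen only after the result was seen, and the others were chosen before the data were examined. Of the values under alternatives, 321 stayed within 1.5 times (counts) or the replicate spread and 160 did not. The named gene Hmmr reversed in FOXO1 on its most variable probe set, at log2 -0.1646. Where the cause is not given by the setting's construction, the cause was not tested. Without 1 array at a time, where a lone array is assumed to vary like the other groups, the ranges were 23 to 195 for light against dark zone, 108 to 524 for FOXO1, 110 to 851 for P110*, 37 to 132 for PTEN, 37 to 155, 48 to 346 and 6 to 37 outside both zones, 7 to 43 for P110* against FOXO1, 75 to 316 for PTEN against FOXO1, 1 to 298 for P110* against PTEN, 44 to 350, 4 to 52 and 12 to 83 for genes shared by FOXO1 and P110*, FOXO1 and PTEN, and P110* and PTEN, 8 to 14, 4 to 7, 9 to 13, 5 to 10 and 0 to 0 for lists, and 0.6048 to 0.8304, 0.6002 to 0.9074 and 0.45 to 0.6678 for the zone positions.

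The most variable probe set gave 61 genes for light against dark zone, 55 for PTEN, 15 for PTEN outside both zones, 126 for P110* against PTEN, 23 shared by FOXO1 and PTEN and 6 lists in P110*. PTEN against FOXO1 gave 270 after quantile normalisation and 297 after median centring. Array weights gave 15 for the zones, 650, 1491 and 178 for FOXO1, P110* and PTEN, 74 and 466 outside both zones for FOXO1 and P110*, 59, 757 and 992 between mutants and 480, 59 and 113 shared. Fits of only the groups compared gave 0, 168, 470 and 19, then 20, 185 and 6 outside both zones, and 0, 0 and 108 between mutants, where limma had 1200 (zones), 1060 (P110* against FOXO1) and 2646 (PTEN against FOXO1) genes at an unadjusted p under 0.05. A linear mix of the zones gave 56 genes shared by FOXO1 and PTEN. Split controls gave 152, 20.7 and 35.7. Lists called with an estimated correlation were 1, 0, 0 and 0, and fry called 3 in FOXO1 and 4 in PTEN. Fixed markers gave zone positions of 0.5213, 0.5427 and 0.73, and without cell cycle genes P110* stood at 0.8113. That setting removed 1 of the 30 dark zone genes and 0 of the 65 light zone genes, so it cannot show how far zone position depends on the cell cycle. The fixed dark zone markers, many of them mitotic genes, were not scored without those. Without both male arrays the zones gave 54, PTEN 141, and shared genes 54 (FOXO1 and PTEN) and 90 (P110* and PTEN). The male covariate gave 174 and 132 for the zones and PTEN, and the actin covariate 264 and 308 for PTEN against FOXO1 and P110* against PTEN.

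The replicate block gave 60 genes for the zones, 215 for FOXO1, 39 for PTEN, 51 and 11 outside both zones for FOXO1 and PTEN, and 139, 14 and 27 shared. The pairing check gave correlations of 0.0444, 0.127 and 0.0709 for numbers 1, 2 and 3, so the numbers were not taken to pair the arrays. The arrays numbered 2, both male, each correlated best with the other, and dark zone array 1 and light zone array 3 did not correlate best with their own number.

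Of the named genes that differed, 8 of 31 kept their call without each array in turn for the zones, 6 of 35 for FOXO1, 21 of 43 for P110*, 5 of 24 for PTEN and 2 of 6 for P110* against FOXO1. In every setting 0 of 31, 5 of 35, 21 of 43, 4 of 24 and 0 of 6 kept it, in the same order. Dim signal limits what could be tested, since 6595 of 18194 genes did not exceed the floor on enough arrays.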

Other observations

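The genes shared by all 3 mutants and the count near Foxo1 between the mutants came from tests chosen only after the result was seen, and the gene lists and the test of genes near Foxo1 did not.

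Genes that differed from the control zones in each of the 3 mutants were 11 higher and 20 lower. Among the higher ones was Id2, an inhibitor of E protein transcription factors, at log2 1.46 in FOXO1, 2.54 in P110* and 1.67 in PTEN, beside Sdc1, Slpi and Ckap4. Among the lower ones were the adhesion receptor Cd2 (-1.27, -2.72 and -1.99), the insulin receptor Insr (-1.40, -1.76 and -1.83), Reln, Nt5e and Gcsam. Independent lists would share 0.00858 and 0.0513 genes. In 100 simulated sets of unchanged mutants with the same controls 0 were shared, but such sets hold few calls to share. The 3 comparisons share their control arrays. Giving each mutant a dark and a light zone array of its own leaves 1 array in each control group, without a spread of its own. Such a fit cannot show how many of the 31 genes come from the shared controls. The 31 genes became 4 without PTEN array 2 or FOXO1 array 2, 7 without PTEN array 1 and 12 without FOXO1 array 1. They became 17 and 16 without P110* arrays 2 and 1, 16 and 18 without dark zone arrays 1 and 3, and 54 with array weights. Reln was the 1 gene of the 31 called in all 3 mutants without each array in turn. Sdc1 was so in 11 of these 12 fits, Cd2 and Ckap4 in 10, Nt5e in 9, Slpi in 7, Id2 and Gcsam in 6 and Insr in 5.

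Members of B cell receptor signalling moved both ways in FOXO1 cells: the adaptor Pik3ap1 was at log2 2.94, while the PI3 kinase subunit Pik3cd (-1.64), the receptor Cd72 (-1.52) and the kinase Syk (-1.17) were lower. In P110*, Pik3ap1 was at log2 1.26 and Pik3cd at -1.35. The glutamine transporter Slc1a5 was lower in FOXO1 (-1.96) and in P110* (-2.08). The list of B cell receptor signalling components was called in none of the 5 comparisons (lowest camera adjusted p = 0.155; adjusted p = 0.695 with an estimated correlation). The lowest camera adjusted p among the 16 of 34 lists called in none was 0.0564, for sterol biosynthesis, and the lowest adjusted p with an estimated correlation was 0.234.

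A hypothesis that variants linked to the targeted locus may account for genes called in FOXO1 was tested on the 100 tested genes nearest to Foxo1. Of these 2% were called against 4.31% of the 441 other genes of the chromosome (Fisher's exact test, one-sided p = 0.925), which argues against linked variants as the source of most genes called in FOXO1. In P110* against FOXO1, 2 of the 8 genes that differed, Gm34303 and 4932438A13Rik, lay among those 100, where 0.069 would be expected. They are the same 2 as in FOXO1, too few to decide, and linked variants stay open for them.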
